A study of Homo sapiens with 18 samples.

How the data were processed

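RNA from HEK293 cells, a human embryonic kidney line, was sequenced in 18 libraries. Per the labels' protocols, cells received 4-thiouridine at 500 µM, a uridine analogue that is built into RNA made after its addition, and the labelled RNA was biotinylated and purified on streptavidin. Labelled RNA after 5 labelling times (7.5, 15, 30, 45 and 60 min) gave 3 libraries each, 15 in all, and total RNA without streptavidin selection gave 3 libraries. Per the file headers, the 3 total libraries differ in how ribosomal RNA was kept out: replicate 1 was selected by oligo-dT (poly(A)), replicate 2 was depleted with RNase H and DNA oligos, and replicate 3 was depleted with Ribo-Zero. The spread of the total group therefore holds the selection method, and its differences from labelled RNA can hold it too. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

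The authors deposited TPM (transcripts per 1000000 transcripts), which carry no read depth. Per the submitters' processing notes, Bowtie 1.0.1, RSEM 1.2.11 and the genome build hg19 were used. Per the file headers, RSEM ran on GENCODE release 19 with 1 extra isoform per gene that spans the whole locus, the primary transcript, and the mature value of a gene is the sum of its other isoforms. For intronless genes the deposited TPM of both kinds are summed. The TPM table had 63568 gene entries, of which 25068 had no primary value. The authors deposited the excised share of introns as a fraction from junction reads counted with bam2ssj, kept where an intron had more than 5 reads in all 3 replicates, and averaged over replicates, per the file headers. The aligner of those junction reads is not given in the sources used here. The authors' intron table also gave log10 intron length, GC fraction, and MaxEnt splice site scores, which were described as deposited. The authors' rate table held centred scores for synthesis, processing and degradation rates estimated with INSPEcT with all labelling times as pseudo-replicates, for the cytoplasmic to nuclear and polysomal to cytosolic balance from other libraries, and for translation from ribosome profiling, per the file headers. The degradation and synthesis scores were checked to be on a log10 scale against the linear rates in the intron table. The log base of the processing score is not stated, so it was used for order only. The authors sorted genes into 7 clusters by k-means on 6 of these measures, per the file headers. Of the copies-per-cell table, only the check in the closing section was made. The exon inclusion levels, 5 columns, were not used here.

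Gene symbols and types came from GENCODE release 29, since the TPM table gives only identifiers: 82.1% of the 63568 identifiers matched, and 90.6% of the 16580 with a mean of at least 1 TPM. No coordinates were moved between builds, and intron positions are those of the authors' table (hg19, counted from 1).

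Mature TPM were compared on the scale log2(TPM + 1), with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3 and Benjamini-Hochberg adjustment at a threshold of 0.05. A log2 change on this scale understates the change of low genes. Labelled comparisons used the 15 labelled libraries together, with genes at a mean of at least 1 TPM, and comparisons with total RNA used all 18. Primary transcripts had the same test on their own. The unspliced share of a gene is its primary TPM as a percent of its primary plus mature TPM, over genes with means of at least 1 TPM mature and 0.1 TPM primary, and the ratio of primary to mature TPM per gene was tested on a log2 scale with a pseudocount of 0.1. Differences between 3 and 3 libraries in 1 value had a two-sided exact permutation test, whose smallest possible p is 0.1. Correlations had 100000 permutations. The 3 total libraries, 1 per method, were compared by values only: a gene with at least 5 TPM in 1 library was counted when the log2 ratios of its TPM + 1 to both depleted libraries were at least 1 in size and of the same sign.

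The 18 gene lists, the tests, the named-gene rule and most alternatives were fixed before the data were examined. The lists were immediate early genes, ribosomal proteins, nuclear-encoded oxidative phosphorylation (OXPHOS) subunits, mitochondrially encoded mRNAs, replication histones, zinc finger genes with ZNF symbols, snoRNA hosts, nuclear lncRNAs, small structured non-coding RNAs, glycolysis, proteasome, heat shock chaperones, ATF4 stress response, p53 targets, SR proteins and CLK kinases, mitotic genes, translation factors, and markers of other cell types. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list's genes rank differently from all others, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, was an alternative. For the authors' rates and the selection methods, a list's median was placed among 10000 random lists of the same size.

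Genes named in the text follow this rule. For labelled 60 min against 7.5 min and for total against labelled 60 min, they are the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p under 0.05, no overlap between the groups and a mean of at least 5 TPM in the higher group, where chance alone separates 3 from 3 libraries in 10% of genes. Added to these are the 2 members of each list with the highest mean TPM, and MYC, FOS, JUN, GAPDH, ACTB, MALAT1 and NEAT1 whatever their result. Primary transcripts had 4 and 4, and the selection comparison had 6 and 6 by the smaller log2 ratio.

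The alternatives were a pseudocount of 0.1 (1 for the ratio), no filter or a filter of 5 TPM, quantile normalization, median-ratio scaling of the libraries, TPM rescaled over mature transcripts alone, fits of the compared groups alone, leaving out each library in turn, the replicate letter as a block, and other list tests. Added after seeing the data were fits without the 45 min replicate 2, a ratio with each kind of transcript scaled on its own, and median-ratio scaling of primary transcripts.

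The tests were checked on simulated data in which 200 genes were changed. For labelled 60 min against 7.5 min (16645 genes), 56% of log2 rises of 2, 68.1% of log2 falls of that size and 14% of log2 rises of 1 were recovered, with 3.75% false calls. The recovered shares of log2 rises of 2 were 48% for total against labelled 60 min (16373 genes, 11.3% false calls), 64% for total against labelled 7.5 min (16402 genes, 8.45%), 92% for primary transcripts (14409 genes, 4.8%), 26% for the ratio (13757 genes, 4%) and 70% for any change over labelling time (16641 genes, 7.35%). With 200 changed genes the adjustment is stricter than with the larger numbers called below. Tables, permutations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.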

Results

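The data were 18 libraries of RNA from HEK293 cells, a human embryonic kidney line, with 3 libraries of newly made (4-thiouridine-labelled) RNA for each of 5 labelling times and 3 libraries of total RNA. The series title names its aim as sorting coding and non-coding genes by their RNA metabolism, and the labelling times follow RNA from minutes to 1 h after it is made. Values are the authors' TPM for mature (spliced) and primary (unspliced) transcripts, and read depth is unknown because TPM do not carry it. The TPM of each labelled library summed to about 1000000, and those of the total libraries to 984390 (poly(A)), 988400 (RNase H) and 988320 (Ribo-Zero). Mature values above 0 were listed for 18318 to 20407 genes in 14 labelled libraries, for 15159 genes in labelled 45 min replicate 2, and for 22906 to 24470 genes in the total libraries. The 10 most abundant mature transcripts held 21.5% of the TPM in the poly(A) library, 42.5% in the RNase H library and 60.5% in the Ribo-Zero library. Primary transcripts held 23.1% ± 0.742 (SD, n = 3) of the TPM at 7.5 min, 9.30% ± 1.95 (SD, n = 3) at 60 min and 0.747% ± 0.190 (SD, n = 3) in total RNA.

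The first comparison asked which spliced RNAs gain or lose weight in labelled RNA as labelling goes on from 7.5 to 60 min. Messenger RNAs of many immediate early and histone genes gained weight, and mRNAs of ribosomal proteins and of nuclear-encoded respiratory chain subunits lost it. MYC, a growth-promoting transcription factor with an unstable mRNA, rose from 143 ± 50.6 TPM at 7.5 min to 460.1 ± 129 TPM at 60 min (SD, n = 3 each). E2F3, a transcription factor of the G1 to S transition, rose from 7.5 ± 1.40 to 94.3 ± 7.99 TPM (SD, n = 3 each). The ribosomal protein mRNA RPS2 fell from 3198 ± 799 to 1031 ± 206 TPM (SD, n = 3 each). COX6B1, a subunit of cytochrome c oxidase, fell from 422 ± 74.7 to 75.1 ± 7.17 TPM (SD, n = 3 each). The summed TPM of ribosomal protein mRNAs was 72858 ± 13909 at 7.5 min and 26938 ± 2444 at 60 min (SD, n = 3 each).

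**Figure D1:**
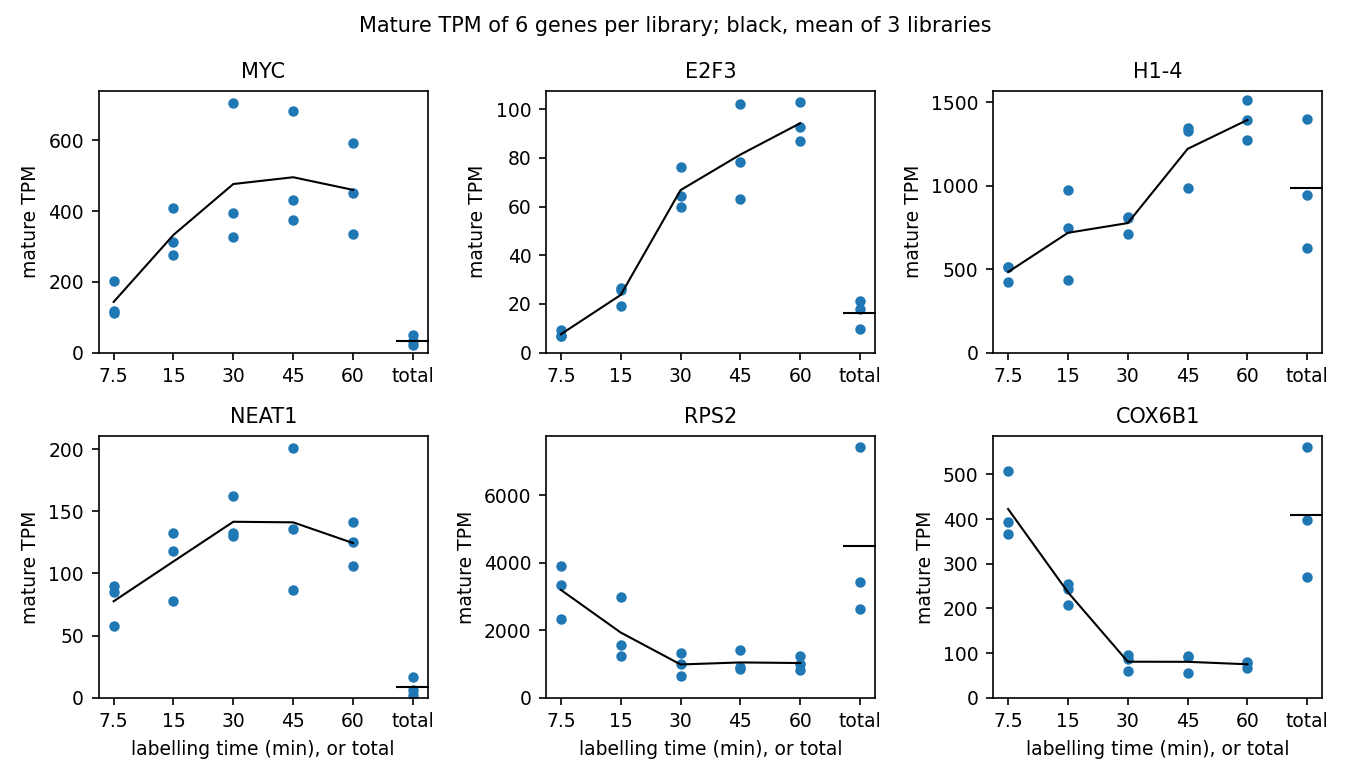
Mature TPM (vertical axes, each from 0) of MYC, E2F3, H1-4, NEAT1, RPS2 and COX6B1 in each library against labelling time in minutes, with total RNA at the right. Points are libraries and black lines are means of 3 libraries; E2F3 goes from 7.5 to 94.3 TPM between 7.5 and 60 min, and COX6B1 from 422 to 75.1 TPM.

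Of 16739 genes tested with limma, 3358 differed between 60 and 7.5 min after Benjamini-Hochberg adjustment, 2653 higher and 705 lower at 60 min. The median log2 change of all genes was 0.24, beside the fall of the primary share of TPM from 23.1% to 9.30%. Median-ratio scaling moved that median to −0.05 and the calls to 1296 higher and 1307 lower, and quantile normalization moved them to 0.01, 1510 higher and 1176 lower. With TPM rescaled over mature transcripts alone the median was 0.03, with 1588 higher and 960 lower. By gene type, 2451 of 12365 protein-coding genes were higher and 500 lower, against 45 higher and 73 lower of 1680 long non-coding genes and 22 higher and 64 lower of 1089 pseudogenes, whose reads can be shared with their parent genes. Over all 5 labelling times, limma's F test called 2720 genes. Against 7.5 min, 8 genes (7 higher, 1 lower) passed limma's test at 15 min, where 1482 had an unadjusted p under 0.05, 1430 (954 higher, 476 lower) at 30 min and 2864 (2066 higher, 798 lower) at 45 min.

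The list medians that follow are log2 changes at 60 against 7.5 min, and none of those of the lists called here changed sign under the 3 scalings. Of 83 ribosomal protein genes, which build the ribosome, 65 fell and 1 rose (71 and 2 adjusted over the list alone). Their median was −1.38, or −1.62 relative to all genes. RPS27 had a log2 change of −2.36 (SE 0.30, limma adjusted p = 8.30e-05). Of 62 nuclear OXPHOS genes, which encode respiratory chain and ATP synthase subunits, 33 fell and 1 rose (38 and 1 adjusted over the list alone). Their median was −1.14, or −1.38 relative to all genes. COX6B1 had a log2 change of −2.47 (SE 0.23, limma adjusted p = 8.87e-06) and COX6A1, another cytochrome c oxidase subunit, of −1.70 (SE 0.24, limma adjusted p = 1.92e-04). Of 20 genes for SR proteins, CLK kinases and partners, which control splice site choice, 11 rose and none fell (14 and 0 adjusted over the list alone). Their median was 0.79, or 0.54 relative to all genes. Among them SRSF2 rose by 0.99 and RBM39 by 0.95 on the log2 scale. With camera these lists had adjusted p of 3.95e-56, 5.53e-25 and 2.48e-06. They were the 3 of 12 called lists whose calls held (adjusted p = 0.0112, 0.00203 and 0.0112 with an estimated correlation). Under median-ratio scaling 71 ribosomal protein and 40 OXPHOS genes fell and 7 SR and CLK genes rose. These 3 calls also held without any 1 of the 6 libraries compared.

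Replication-dependent histones, whose mRNAs end in a stem loop instead of a poly(A) tail, had 28 of 32 members higher at 60 min and none lower (28 and 0 adjusted over the list alone). Their median was 1.65, or 1.41 relative to all genes. H1-2 rose by 1.37 and H1-4 by 1.53 on the log2 scale, H1-4 from 482 ± 52.4 to 1393 ± 121 TPM (SD, n = 3 each). The camera adjusted p of this list was 1.58e-17 and adjusted p = 0.0981 with an estimated correlation. Of 32 immediate early genes, which respond first to growth signals, 14 rose and none fell (21 and 0 adjusted over the list alone), with a median of 1.33, or 1.09 relative to all genes. The camera adjusted p was 8.00e-07 (adjusted p = 0.292 with an estimated correlation). MYC had a log2 change of 1.69 (SE 0.32, limma adjusted p = 0.00184), whereas JUN, a subunit of the AP-1 factor, did not pass (log2 change 0.60, limma adjusted p = 0.13). FOS had 5.47 ± 0.695 TPM at 60 min and 6.20 ± 3.93 TPM at 7.5 min (SD, n = 3 each) and did not pass. Of 428 zinc finger genes with ZNF symbols, many of them DNA-binding repressors, 168 rose and 3 fell (192 and 3 adjusted over the list alone), with a median of 0.81, or 0.57 relative to all genes. The camera adjusted p was 8.55e-11 (adjusted p = 0.128 with an estimated correlation). ZNF703 rose from 154 ± 63.8 to 518 ± 122 TPM (SD, n = 3 each), while ZNF207 had 268 ± 29.6 and 320 ± 11.4 TPM and did not pass. Under median-ratio scaling 23 histones, 9 immediate early genes and 94 zinc finger genes rose. Without 7.5 min replicate 2 or replicate 3 only 9 immediate early genes rose.

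Stress and cell cycle genes also stood above the median of all genes. In the ATF4 stress response list 10 of 17 members rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.18. The camera adjusted p was 2.14e-04, and adjusted p = 0.157 with an estimated correlation. ATF4 itself rose by 1.06 on the log2 scale, and the chaperone HSPA5 rose from 67.2 ± 3.02 to 155 ± 9.13 TPM (SD, n = 3 each). Of 17 p53 targets 7 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.80. Camera gave them an adjusted p of 0.0253, and adjusted p = 0.0981 with an estimated correlation. Among them were MDM2, which degrades p53 (log2 change 0.97), and the death receptor TNFRSF10B (0.71). Of 22 mitotic genes 11 rose and none fell (13 and 0 adjusted over the list alone), with a median of 0.67, and MKI67 rose by 0.89 and AURKB by 0.74 on the log2 scale. The camera adjusted p of mitotic genes was 5.34e-04, and adjusted p = 0.157 with an estimated correlation. Under median-ratio scaling 5 ATF4 stress response genes, 3 p53 targets and 5 mitotic genes rose, with medians of 0.85, 0.53 and 0.32. Quantile normalization gave 7, 3 and 5, and TPM rescaled over mature transcripts alone gave 8, 3 and 4. Without 7.5 min replicate 1 only 4 p53 targets rose, and without 60 min replicate 3 only 3 p53 targets and 7 mitotic genes.

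Of the 13 mRNAs encoded in mitochondrial DNA 6 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.69, or 0.45 relative to all genes. Under quantile normalization 1 rose (median 0.21), under median-ratio scaling none (0.34) and with TPM rescaled over mature transcripts alone 2 (0.45). With camera the adjusted p was 0.00680, and adjusted p = 0.292 with an estimated correlation. MT-ND1 had 12756 ± 3368 TPM at 7.5 min and 22837 ± 5869 TPM at 60 min (SD, n = 3 each) and did not pass (limma adjusted p = 0.0552). MT-ATP6 had a log2 change of 0.19 that all 3 scalings turned negative. Of 33 proteasome genes 7 fell and 2 rose (the same numbers adjusted over the list alone), with a median of −0.22, or −0.46 relative to all genes. Their camera adjusted p was 3.91e-04, and adjusted p = 0.159 with an estimated correlation. PSMD8 fell (log2 change −0.73), and PSMB4 did not pass (−0.21). Of 17 glycolysis genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of −0.31, or −0.56 relative to all genes. For this list camera gave an adjusted p of 0.00763, and adjusted p = 0.189 with an estimated correlation. GAPDH, a glycolytic enzyme, did not pass (log2 change −0.58, limma adjusted p = 0.0993). Median-ratio scaling gave 12 proteasome and 7 glycolysis genes lower. Without 60 min replicate 1 only 1 mitochondrial mRNA rose, and 3 rose without 7.5 min replicate 2 or 60 min replicate 2. Without 7.5 min replicate 3 only 4 proteasome genes fell. No glycolysis gene fell without 7.5 min replicate 1, 7.5 min replicate 3 or 60 min replicate 1, and 1 fell without 60 min replicate 2 or 3.

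The remaining lists were not called by camera. Of 25 snoRNA host genes, whose introns carry small nucleolar RNAs, 7 rose and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0784). Of 13 heat shock chaperones 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.144), and HSPA8 rose by 0.64 while HSP90AA1 did not pass. Of 56 translation factors 19 rose and 4 fell (20 and 4 adjusted over the list alone; camera adjusted p = 0.101), and EIF4A1, a helicase that opens mRNA for translation, rose by 0.72. Of 9 nuclear lncRNAs 1 rose (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.119). MALAT1, a nuclear speckle RNA, had 328 ± 74.2 and 561 ± 308 TPM at 7.5 and 60 min (SD, n = 3 each). NEAT1, the scaffold of paraspeckles, had 77.6 ± 17.5 and 124 ± 17.7 TPM, and JPX had 161 ± 51.4 and 77.1 ± 35.5 TPM. None of these lncRNAs passed. Of 45 small structured RNAs 3 rose and none fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.225). SNORD3A had 1026 ± 505 and 733 ± 87.3 TPM and RNU2-2P, a U2 spliceosomal RNA gene, 211 ± 71.3 and 314 ± 138 TPM at 7.5 and 60 min (SD, n = 3 each). None of ACTB, ENO1, EEF1A1, TAF1D and SNHG29 passed. ACTB had 805 ± 204 and 646 ± 94.4 TPM, ENO1 797 ± 87.4 and 734 ± 43.9 TPM, and EEF1A1 1805 ± 286 and 1713 ± 180 TPM. TAF1D had 366 ± 71.8 and 418 ± 53.9 TPM, and SNHG29 261 ± 68.9 and 256 ± 6.02 TPM. Of markers of other cell types only HBA1 (6.61 and 1.56 TPM) and COL1A1 (1.42 and 1.27 TPM) reached the expression filter, and neither passed. With median-ratio scaling 3 snoRNA hosts, 1 heat shock chaperone and 11 translation factors rose, and 2 snoRNA hosts, 2 heat shock chaperones, 7 translation factors and 4 nuclear lncRNAs fell. The snoRNA hosts passed camera without 7.5 min replicate 1 (adjusted p = 0.0376), 7.5 min replicate 3 (0.0451) or 60 min replicate 2 (0.0401), and 4 of them rose without 7.5 min replicate 2 or 60 min replicate 1. Translation factors passed camera without 7.5 min replicate 3 (adjusted p = 0.0451) or 60 min replicate 1 (0.0372). Only 3 heat shock chaperones rose without 7.5 min replicate 2 or 3 or 60 min replicate 3, and 1 small structured RNA rose without 7.5 min replicate 1 or 2 or 60 min replicate 3.

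**Figure D2:**
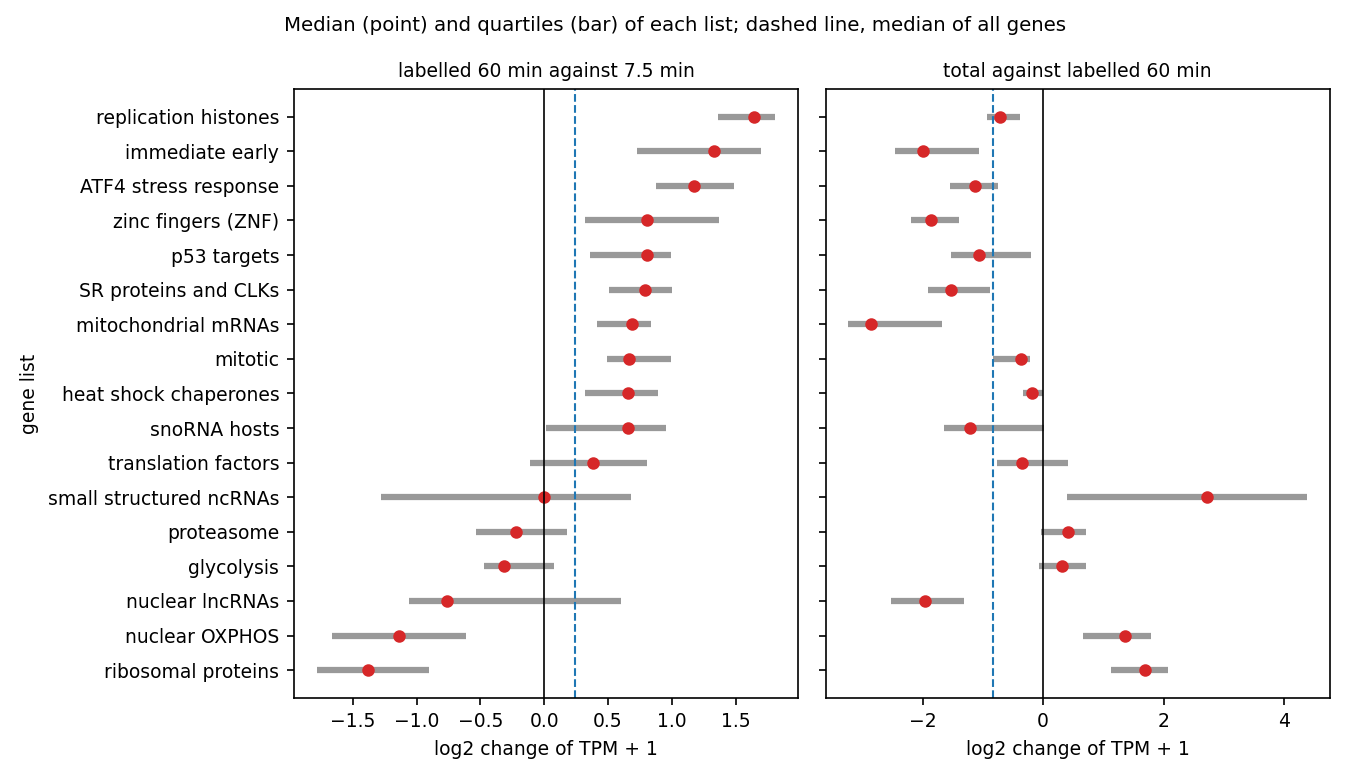
Median (point) and quartiles (bar) of the log2 change of mature TPM + 1 in 17 gene lists, for labelled 60 min against 7.5 min (left) and total RNA against labelled 60 min (right), with the median of all genes dashed (0.24 and −0.84). Ribosomal proteins lie at −1.38 on the left and 1.69 on the right; on the right the medians of heat shock chaperones, mitotic genes, histones and translation factors turn positive with median-ratio scaling.

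The largest single rises at 60 min included MIS12, a kinetochore subunit (log2 change 3.61, SE 0.41, limma adjusted p = 4.31e-05), ZNF304 (3.60) and ZNF628 (3.58). E2F3 had a log2 change of 3.50 (SE 0.22, limma adjusted p = 8.52e-07). The pseudogene GUSBP14 was listed at 0 in all libraries at 7.5 min and at 33.9, 31 and 27.96 TPM at 60 min, and the small Cajal body RNA SCARNA10 at 0, 0 and 5.3 TPM and then at 22.72, 34.48 and 38.24 TPM. The largest falls included PET100, an assembly factor of cytochrome c oxidase, from 34.4 ± 10.3 to 2.44 ± 1.83 TPM (SD, n = 3 each, log2 change −3.47, limma adjusted p = 0.00135). SUMO4, an intronless gene close in sequence to SUMO2, had a log2 change of −3.72. The others were DHFRP1 (61.32, 26.14 and 58.15 TPM at 7.5 min, and 13.62, 0 and 0 at 60 min), RPL7AP22 (24.5, 9.44 and 20.38 TPM, and 0, 0.28 and 0), PHKA1P1 (−3.28) and RN7SL76P (25.34, 9.88 and 9.72 TPM, and 0, 3.46 and 0). Values of pseudogenes and near copies such as these are uncertain, since their reads can be split with the genes they resemble.

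The next question was how fast primary transcripts turn into mature ones. At 7.5 min a typical gene had 38.9% ± 0.527 of its TPM in the unspliced form, which went to 37.1% ± 3.43 at 15 min, 28.6% ± 2.44 at 30 min, 18.4% ± 3.67 at 45 min and 14.8% ± 3.07 at 60 min (medians over 13757 genes, SD, n = 3 each). In total RNA the share was 2.59% ± 0.637 (SD, n = 3). The ratio of unspliced to spliced RNA was lower at 60 than at 7.5 min in most immediate early, ATF4 stress response and mitotic genes. In ribosomal protein and OXPHOS genes about as many ratios rose as fell. The share at 60 min lay 24.1 points below that at 7.5 min (difference −24.1, two-sided exact permutation test, p = 0.1, the smallest that 20 arrangements allow). Across the 15 labelled libraries the share followed labelling time with Pearson r = −0.961 and Spearman rho = −0.927, each with a permutation p = 1e-05 (the smallest that 100000 permutations can give; adjusted p = 1e-05 over 4 relations), and r ranged from −0.967 to −0.948 without the 2 farthest libraries, for which 3 tied.

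**Figure D3:**
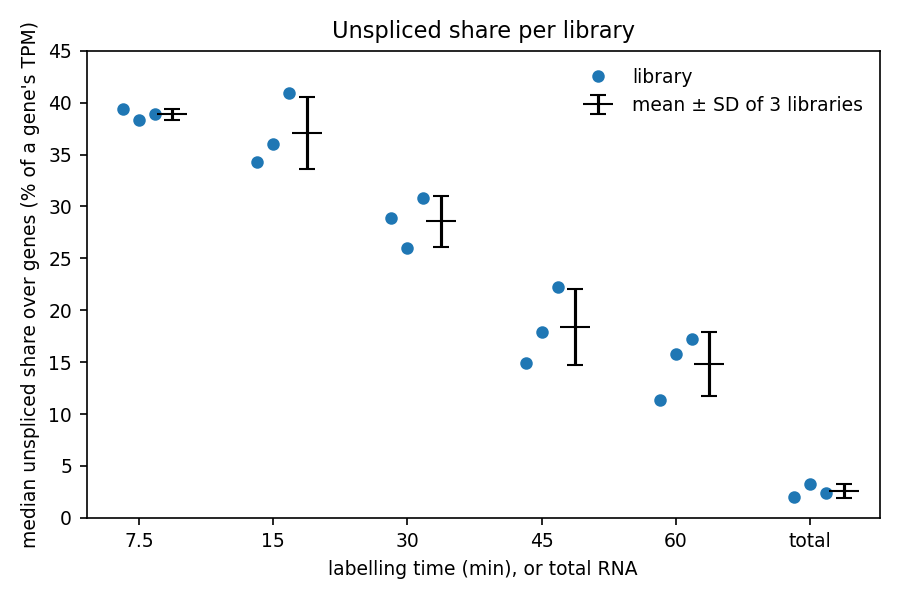
Median unspliced share per library (vertical axis, percent of a gene's TPM, over 13757 genes) by labelling time in minutes and in total RNA. Points are libraries and crosses are means with SD of 3 libraries, from 38.9% at 7.5 min to 14.8% at 60 min and 2.59% in total RNA.

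Of 14497 primary transcripts tested with limma, 10874 were lower and 92 higher at 60 than at 7.5 min, with a median log2 change of −1.15. This fall is relative to all RNA in the library: with median-ratio scaling over primary transcripts, chosen after seeing the data, the median was 0.04 and 3175 were higher and 3154 lower, and with quantile normalization the median was −0.06, with 2667 higher and 3709 lower. HOXB6, a homeobox gene, had the largest rise (0.35 ± 0.606 to 36.3 ± 2.83 TPM, SD, n = 3 each), ahead of TM9SF1 (log2 change 2.37), ATP2A1-AS1 (1.70) and BLOC1S3 (1.64). NUDT3 (17.1 ± 3.43 to 0.00667 ± 0.0115 TPM, SD, n = 3 each), STAG3L5P (−3.88), BTF3L4P2 (−3.49) and PRR4 (−3.42) fell most. The primary isoform covers the whole locus, so reads of overlapping or neighbouring genes can add to it. All 22 mitotic genes were lower, with a median of −1.66. Relative to all genes this was −0.51 (camera adjusted p = 0.00323; adjusted p = 0.92 with an estimated correlation). Camera also called 3 other lists. Of 10 histones 3 were lower and 2 higher (3 and 1 adjusted over the list alone), with a median of −0.32, which was 0.83 above all genes and turned to 0.84 with median-ratio scaling and 0.74 with quantile normalization (camera adjusted p = 9.28e-05; adjusted p = 0.429 with an estimated correlation). Of 75 ribosomal protein genes 66 were lower (67 adjusted over the list alone), with a median of −1.17, which was −0.02 relative to all genes and turned to 0.26 with median-ratio scaling (camera adjusted p = 0.00501; adjusted p = 0.92 with an estimated correlation). Of 12 heat shock chaperones 11 were lower (11 adjusted over the list alone), with a median of −1.79, or −0.64 relative to all genes (camera adjusted p = 0.0249; adjusted p = 0.92 with an estimated correlation). Median-ratio scaling gave 8 mitotic genes and 5 heat shock chaperones lower, and 2 of the chaperones and 13 ribosomal protein genes higher. Heat shock chaperones lost camera's call without 60 min replicate 2 (adjusted p = 0.0515; adjusted p = 0.919 with an estimated correlation), and 1 histone was higher on leaving out any 1 of 7.5 min replicates 1, 2 and 3 and 60 min replicates 1 and 3. Camera called ATF4 targets without 7.5 min replicate 2 (adjusted p = 0.0302), 7.5 min replicate 3 (0.0181) or 60 min replicate 1 (0.0176). Without 7.5 min replicate 2 it also called SR and CLK genes (0.0302), translation factors (0.0180) and immediate early genes (0.0488), and without 60 min replicate 1 SR and CLK genes (0.0485) and translation factors (0.0426).

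The ratio of unspliced to spliced TPM per gene, tested with limma in 13757 genes, was lower at 60 min in 8725 and higher in 150, with a median log2 change of −1.81. With each kind of transcript scaled on its own, added after seeing the data, 2072 were lower and 1789 higher, with a median of 0.03. Of 24 immediate early genes 21 were lower, with a median of −2.94, which was −1.12 relative to all genes. All 22 mitotic genes (−2.54), all 19 SR and CLK genes (−2.28) and 14 of 16 ATF4 stress response genes (−2.98) were lower too. Adjusted over the list alone these counts were the same. Camera adjusted p were 0.00292 for immediate early, 2.34e-05 for mitotic, 3.87e-04 for SR and CLK and 0.0145 for ATF4 genes. The first 3 had an adjusted p = 0.356 with an estimated correlation, and the ATF4 list had an adjusted p = 0.393 with an estimated correlation. Of 75 ribosomal protein genes 14 were lower and 14 higher (13 and 14 adjusted over the list alone), with a median of 0.23, which was 2.05 above all genes. Of 58 OXPHOS genes 12 were lower and 10 higher (9 and 10 adjusted over the list alone), with a median of 0.38, which was 2.19 above all genes. Camera called both (adjusted p = 8.54e-26 and 3.53e-18), and neither call held (adjusted p = 0.113 and 0.0561 with an estimated correlation). With each kind of transcript scaled on its own, 62 ribosomal protein and 41 OXPHOS genes were higher, and 10 immediate early, 8 mitotic, 6 SR and CLK and 8 ATF4 genes were lower. Among 25 snoRNA hosts 12 were lower (9 adjusted over the list alone), with a median of −1.44 that turned to 0.40 with each kind scaled on its own. Among 33 proteasome genes 23 were lower and 2 higher (the same adjusted over the list alone), with a median of −0.95 that turned to 0.90 in the same way. Neither list was called (camera adjusted p = 0.602 and 0.552). Camera did call 3 more lists. Of 422 zinc finger genes 346 were lower (354 adjusted over the list alone), with a median of −2.25, or −0.44 relative to all genes (camera adjusted p = 1.95e-04; adjusted p = 0.615 with an estimated correlation). Of 56 translation factors 46 were lower (46 adjusted over the list alone), with a median of −1.84 that turned to 0.00393 with each kind scaled on its own (camera adjusted p = 0.0185; adjusted p = 0.665 with an estimated correlation). Of 13 heat shock chaperones 11 were lower (11 adjusted over the list alone), with a median of −2.25, or −0.44 relative to all genes (camera adjusted p = 0.0445; adjusted p = 0.487 with an estimated correlation). With each kind scaled on its own 95 zinc finger genes were lower and 17 higher, 10 translation factors lower and 9 higher, and 5 heat shock chaperones lower and 1 higher. Without 7.5 min replicate 1 the ribosomal protein and OXPHOS calls held (adjusted p = 0.0309 and 0.0327 with an estimated correlation), and 8 ribosomal protein genes were lower. Heat shock chaperones lost camera's call without 7.5 min replicate 2 (adjusted p = 0.0874; adjusted p = 0.565 with an estimated correlation), 60 min replicate 2 (0.0648; adjusted p = 0.576 with an estimated correlation) or 60 min replicate 3 (0.0798; adjusted p = 0.604 with an estimated correlation).

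The same question can be put to single introns, for which the authors' deposited table gives the excised share as a mean of 3 replicates, with no error. Over 21782 introns of 4163 genes in the authors' deposited table the mean excised share was 54.4% at 7.5 min, 57.4% at 15 min, 67.5% at 30 min, 77.5% at 45 min and 81.3% at 60 min. The authors' deposited table sorts 8573 introns (39.4%) as fast, 9357 (43.0%) as medium and 3852 (17.7%) as slow, and the slow class went from a median of 37.4% at 7.5 min to 63.8% at 60 min. Alternative introns made up 11.4% of the slow and 3.46% of the fast class in the authors' deposited table, and median GC content was 44.5% and 40.9%. Introns of MYC were removed during the hour: in the authors' deposited table the intron on chromosome 8 at 128748870 to 128750493 (hg19) went from 27.8% to 92.0% and that at 128751266 to 128752641 from 14.9% to 88.3%. SR and CLK genes went from a median of 36.0% to 79.8% (112 introns) and zinc finger genes from 41.8% to 79.5% (188 introns) in the authors' deposited table. Introns of the 13 genes of the snoRNA host list had 55 of 60 in the slow class, with a median of 19.3% at 7.5 min and 51.3% at 60 min in the authors' deposited table. The introns marked as snoRNA hosts in the authors' deposited table, 162 in 82 genes, had 79 in the slow class and a median of 47.4% at 7.5 min and 71.9% at 60 min. Ribosomal protein introns followed another course in the authors' deposited table, with a median of 74.96% at 7.5 min, 62.8% at 30 min and 76.9% at 60 min. In the authors' deposited table, of 307 ribosomal protein introns 276 were lower at 30 than at 7.5 min, against 4053 of all 21782. In RPS2 the intron on chromosome 16 at 2013258 to 2014276 (hg19) stood at 47.4%, 10.8% and 20.5% at 7.5, 30 and 60 min in the authors' deposited table. The COX6A1 intron on chromosome 12 at 120876325 to 120878256 stood at 86.7%, 55.4% and 69.0% in the authors' deposited table.

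**Figure D4:**
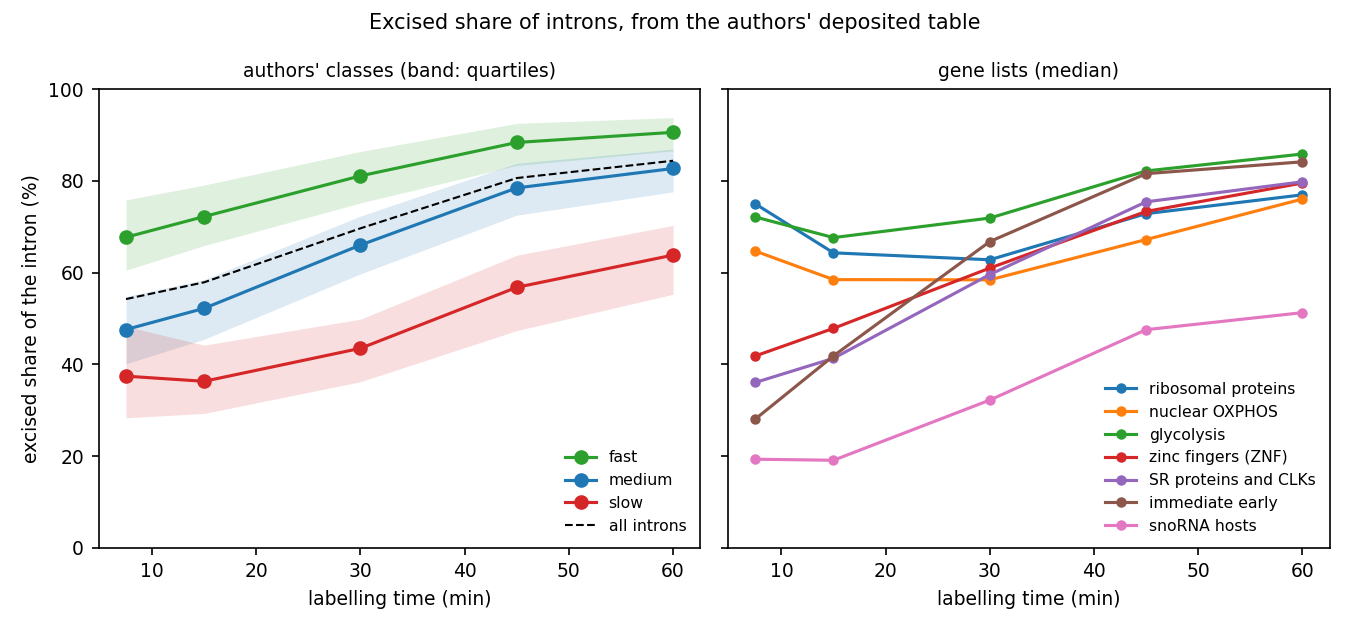
Excised share of introns (percent, vertical axes) against labelling time in minutes, from the authors' deposited table: the authors' 3 classes with a band for the quartiles and all introns dashed (left), and list medians (right). Slow introns go from 37.4% to 63.8%; ribosomal protein introns stand at 74.96%, 62.8% and 76.9% at 7.5, 30 and 60 min.

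Total against labelled RNA at 60 min asks which RNAs pile up in the cell relative to how much of them is newly made. Ribosomal protein, OXPHOS and small structured RNAs weighed more in total RNA, and most zinc finger, immediate early, SR and CLK genes and nuclear lncRNAs weighed less. NEAT1 went from 124 ± 17.7 TPM in labelled RNA to 8.39 ± 7.76 TPM in total RNA, and MYC from 460.1 ± 129 to 33.9 ± 14.2 TPM (SD, n = 3 each). RPS2 had 4494 ± 2568 TPM in total RNA against 1031 ± 206 TPM in labelled RNA, and GAPDH 2869 ± 1296 against 942 ± 173 TPM (SD, n = 3 each). Each total library was made with another selection method, so the SD of the total group includes that difference.

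With limma, 7522 of 16580 genes differed, 869 higher and 6653 lower in total RNA, with a median log2 change of −0.84. Median-ratio scaling moved the median to −0.06 and the calls to 2856 higher and 2517 lower. Quantile normalization moved them to −0.05, 2276 higher and 2511 lower, so the list changes are also given relative to all genes. Ribosomal proteins had 71 of 83 members higher and 3 lower (73 and 3 adjusted over the list alone), with a median of 1.69, which was 2.53 above all genes. OXPHOS genes had 39 of 62 higher and 1 lower (41 and 2 adjusted over the list alone), with a median of 1.36, which was 2.20 above all genes. COX6B1 rose by 2.37 (SE 0.28, limma adjusted p = 5.10e-06). Small structured RNAs had 33 of 62 higher and 1 lower (34 and 1 adjusted over the list alone), with a median of 2.72, which was 3.56 above all genes. Camera adjusted p for these lists were 2.38e-64, 3.59e-32 and 5.00e-35. They were the 3 of 10 called lists that held (adjusted p = 0.0217, 0.0217 and 0.00359 with an estimated correlation). The largest rises were small RNAs at 0 in all 60 min and most other labelled libraries, so they need not show accumulation. In the order poly(A), RNase H and Ribo-Zero, SNORA73B had 135.4, 473.66 and 227.1, and SNORD17 53.22, 266.06 and 326.04 TPM. SCARNA13 had 38.94, 112.86 and 200.44, and SCARNA12 41.9, 77.7 and 191.64 TPM. The U4 gene RNU4-1 had 77.16, 183.04 and 43.58, and the mitochondrial valine tRNA MT-TV 42.48, 76.96 and 104.5 TPM. RNU2-2P rose by 2.15 (log2). These 3 lists also held without any 1 of the 6 libraries compared.

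Zinc finger genes had 366 of 427 members lower in total RNA and none higher (378 and 0 adjusted over the list alone), with a median of −1.86, or −1.02 relative to all genes. The list had a camera adjusted p of 3.10e-19, and adjusted p = 0.142 with an estimated correlation. ZNF703 had a log2 change of −3.91 and ZNF711 of −1.19. Of 32 immediate early genes 24 were lower (25 adjusted over the list alone), with a median of −1.99, or −1.15 relative to all genes. Their camera adjusted p was 6.81e-05, and adjusted p = 0.546 with an estimated correlation. MYC had a log2 change of −3.77 (SE 0.36, limma adjusted p = 7.00e-07) and JUN of −2.26, while FOS did not pass (−1.08). Of 20 SR and CLK genes 16 were lower (17 adjusted over the list alone), with a median of −1.52, or −0.69 relative to all genes. As a set they had a camera adjusted p of 1.98e-04, and adjusted p = 0.286 with an estimated correlation. RBM39 had a log2 change of −1.99 and SRSF2 of −1.56. Of 9 nuclear lncRNAs 7 were lower (7 adjusted over the list alone), with a median of −1.97, or −1.13 relative to all genes. By camera the adjusted p was 0.0233, and adjusted p = 0.546 with an estimated correlation. NEAT1 had a log2 change of −4.10 (SE 0.46, limma adjusted p = 2.56e-06) and MALAT1 of −2.06, which without the Ribo-Zero library was −1.44 and no longer passed. Median-ratio scaling gave 225 zinc finger genes, 17 immediate early genes, 9 SR and CLK genes and 4 nuclear lncRNAs lower. The SR and CLK call held without the poly(A) library (adjusted p = 0.0402 with an estimated correlation).

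Glycolysis genes had 5 of 17 members higher and 1 lower (the same adjusted over the list alone), with a median of 0.31, which was 1.15 above all genes. Proteasome genes had 7 of 33 higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.41, which was 1.25 above all genes. Their camera adjusted p were 1.51e-06 and 4.05e-10, and adjusted p = 0.203 for both with an estimated correlation. GAPDH rose by 1.53 and PSMD8 by 1.67 on the log2 scale, and PSMA4 did not pass (0.71). Translation factors had 8 of 56 higher and 16 lower (the same adjusted over the list alone). Their median of −0.36 turned to 0.64 with median-ratio scaling and 0.21 with quantile normalization. Camera, in contrast to the sign of that median, placed the list above other genes (adjusted p = 0.00815; adjusted p = 0.668 with an estimated correlation). EEF1A1, an elongation factor, had a log2 change of 1.12. Median-ratio scaling gave 15 glycolysis genes, 29 proteasome genes and 27 translation factors higher, with medians of 1.32, 1.41 and 0.64, and quantile normalization gave 7, 19 and 13. Without the poly(A) library the glycolysis and proteasome calls held (adjusted p = 0.0421 for both with an estimated correlation), though their medians were 0.0423 and 0.13 and only 4 proteasome genes were higher, with 3 lower. Translation factors then lost camera's call (adjusted p = 0.0687; adjusted p = 0.560 with an estimated correlation). Without 60 min replicate 1 proteasome genes had 4 higher, and without the RNase H library 11.

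The other lists were not called by camera here. Of the 13 mitochondrially encoded mRNAs 8 were lower (8 adjusted over the list alone), with a median of −2.85 (camera adjusted p = 0.415). Their summed TPM was 135040 in the poly(A), 115490 in the RNase H and 2301.8 in the Ribo-Zero library, against 165780 ± 22621 at 60 min (SD, n = 3). Without the Ribo-Zero library their median was −0.66, which was 0.01 above all genes, with 4 lower and 1 higher. Without 60 min replicate 1, 2 or 3 the lower were 3, 2 and 3, and camera called the list without the poly(A) library (adjusted p = 0.0493) or the RNase H library (0.0330). MT-ND1 (−4.24, or −1.62 without the Ribo-Zero library) and MT-ND6 (−4.40, or −2.90) were among the largest falls, with MTND2P28 (−5.63), a nuclear pseudogene close to mitochondrial sequence. MT-CO1 and MT-ATP6 did not pass (−1.41 and −2.80). The largest fall was that of the mitochondrial ribosomal RNA MT-RNR1, at 664.8, 0.34 and 0.24 TPM in the poly(A), RNase H and Ribo-Zero libraries, the last 2 of which were depleted of ribosomal RNA. LINC02226 stood at 0, 0.59 and 0.06 TPM against 53.6 ± 26.1 TPM at 60 min (SD, n = 3), and MIR3648-2 had a log2 change of −4.49. Histones had 11 of 32 members lower (6 adjusted over the list alone), with a median of −0.72 that turned to 0.29 with median-ratio scaling (camera adjusted p = 0.959). Without the poly(A) library 5 were lower, with a median of −0.30 that camera placed above other genes (adjusted p = 0.0209), and without the Ribo-Zero library 16, with a median of −1.02 that it placed below them (0.00908). Without 60 min replicate 1 the number was 5 and without replicate 3 it was 7. H1-4 had 988 ± 387 and H4C15 1059 ± 744 TPM in total RNA (SD, n = 3 each), and neither passed. ATF4 targets had 10 of 17 lower (10 lower and 1 higher adjusted over the list alone), with a median of −1.13 (camera adjusted p = 0.337). The p53 targets had 9 of 17 lower (9 adjusted over the list alone), with a median of −1.07, and mitotic genes 4 of 22 (4 adjusted over the list alone), with a median of −0.37 that turned to 0.63 with median-ratio scaling. Their camera adjusted p were both 0.579. ATF4 (−1.16), HSPA5 (−1.03), MDM2 (−1.07), TNFRSF10B (−1.52) and MKI67 (−1.60) were lower. Without the Ribo-Zero library MKI67 had a change of −0.77, and HSPA5 (−0.51) and MDM2 (−0.85) no longer passed. The snoRNA hosts had 3 of 26 higher and 12 lower (5 and 12 adjusted over the list alone), and SNHG29 (0.55) and SNHG3 (0.85) did not pass. Their median of −1.22 and mean of −0.70 differed in sign from camera's direction (adjusted p = 0.959). Heat shock chaperones had 2 of 13 higher and 2 lower (the same adjusted over the list alone), with a median of −0.18 that turned to 0.83 with median-ratio scaling (camera adjusted p = 0.0808). Without the Ribo-Zero library it turned to 0.16 and camera called the list (adjusted p = 0.0178), as it did without 60 min replicate 3 (0.0369). With median-ratio scaling 1 mitochondrial mRNA, no histone, 3 ATF4 and 4 p53 targets, 5 snoRNA hosts and 1 heat shock chaperone were lower. Higher were 1 histone, 3 ATF4 and 4 p53 targets, 7 snoRNA hosts, 8 mitotic genes and 5 heat shock chaperones. Of mitotic genes 7 were lower without the poly(A) library.

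HSPA8 had 1231 ± 334 TPM in total RNA and 1296 ± 190 TPM at 60 min, and HSP90AA1 had 990.2 ± 484 and 1109 ± 491 TPM (SD, n = 3 each). TOP2A had 171 ± 38.3 and 206 ± 65.3 TPM, and EEF2 had 1069 ± 325 and 908 ± 118 TPM (SD, n = 3 each). ACTB had 934 ± 352 and 646 ± 94.4 TPM, and SNORD3A had 1013 ± 1262 and 733 ± 87.3 TPM (SD, n = 3 each). None of these passed. ENO1 had 1248 ± 391 and 734 ± 43.9 TPM and passed (log2 change 0.72, limma adjusted p = 0.0271), though quantile normalization turned its change to −0.0280 and without the poly(A) library it was 0.49 and no longer passed. The blood marker HBA1 had 10.8 ± 7.27 against 1.56 ± 1.93 TPM (SD, n = 3 each, limma adjusted p = 0.0587), and the fibroblast marker COL1A1 1.88 ± 1.56 against 1.27 ± 1.18 TPM.

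Total against labelled RNA at 7.5 min puts the same question, but unlabelled RNA carried over, left open below, can hide a rise. OXPHOS genes had 2 of 62 members higher and 1 lower (0 and 1 adjusted over the list alone), with a median of 0.10 that turned to −0.25 with TPM rescaled over mature transcripts alone and to −0.17 without the poly(A) library. Relative to all genes it was 0.56 (camera adjusted p = 4.32e-04; adjusted p = 0.408 with an estimated correlation). With limma, 601 genes were higher and 4163 lower of 16580, with a median of −0.46. Median-ratio scaling gave 2935 higher and 2702 lower (median 0.05), and quantile normalization 2299 and 2369 (median 0.09). Without the poly(A) library 314 were higher and 4656 lower. Small structured RNAs had 35 of 62 members higher and 1 lower (35 and 3 adjusted over the list alone), with a median of 2.94. Camera's call (adjusted p = 6.33e-30) held (adjusted p = 0.00679 with an estimated correlation). Without the Ribo-Zero library it did not (adjusted p = 0.0800 with an estimated correlation). Of 32 histones 14 were higher (17 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 2.96e-14; adjusted p = 0.408 with an estimated correlation). Ribosomal proteins had 11 of 83 higher and 3 lower (9 and 1 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 2.49e-10; adjusted p = 0.408 with an estimated correlation). Of 9 nuclear lncRNAs 6 were lower (8 adjusted over the list alone), with a median of −2.83 (camera adjusted p = 4.41e-04; adjusted p = 0.408 with an estimated correlation). Of 427 zinc finger genes 187 were lower and 3 higher (204 and 3 adjusted over the list alone), with a median of −0.89 (camera adjusted p = 1.30e-06; adjusted p = 0.408 with an estimated correlation). Median-ratio scaling gave 56 ribosomal protein genes, 21 OXPHOS genes and 21 histones higher and 118 zinc finger genes lower (zinc finger median −0.34). Quantile normalization gave 4 ribosomal protein genes higher and 4 lower, with a median of 0.05, which was −0.05 relative to all genes, and 101 zinc finger genes lower (median −0.23). With TPM rescaled over mature transcripts alone the ribosomal protein median was 0.00292, with 4 higher and 5 lower. Without the poly(A) library 23 histones were higher, a call that then held (adjusted p = 0.0383 with an estimated correlation), and 9 were higher without the Ribo-Zero library, 7.5 min replicate 2 or 7.5 min replicate 3. Of ribosomal protein genes 5 were higher and 4 lower without the poly(A) library, with a median of 0.0520, and 4 higher and 1 lower without 7.5 min replicate 2. No OXPHOS gene was higher and 5 were lower without the poly(A) library, and without 7.5 min replicate 2 their median turned to −0.0540.

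Camera placed 6 more lists above other genes. Mitotic genes had 4 of 22 higher (1 adjusted over the list alone), with a median of 0.20, and translation factors 6 of 56 higher and 8 lower (the same adjusted over the list alone), with a median of 0.15. Camera gave adjusted p of 2.59e-04 and 5.03e-05, and adjusted p = 0.408 for both with an estimated correlation. Proteasome genes had 2 of 33 higher and 1 lower (1 and 0 adjusted over the list alone), with a median of 0.0846, and glycolysis genes 3 of 17 higher and 1 lower (the same adjusted over the list alone), with a median of 0.29. Their camera adjusted p were 4.41e-04 and 0.00195, and adjusted p = 0.408 for both with an estimated correlation. No heat shock chaperone of 13 passed, with or without adjustment over the list alone, and their median was 0.48 (camera adjusted p = 0.00183; adjusted p = 0.408 with an estimated correlation). Of 17 ATF4 targets 1 was higher (none adjusted over the list alone), with a median of 0.0576 (camera adjusted p = 0.0416; adjusted p = 0.553 with an estimated correlation). Relative to all genes these 6 medians were 0.66, 0.61, 0.55, 0.75, 0.94 and 0.52. With TPM rescaled over mature transcripts alone the medians of mitotic, translation factor, proteasome, glycolysis and ATF4 genes turned to −0.14, −0.19, −0.26, −0.0487 and −0.27. Without the poly(A) library those of mitotic, translation factor, proteasome and ATF4 genes turned to −0.0549, −0.0788, −0.14 and −0.33. Under median-ratio scaling 15 mitotic, 29 translation factor, 20 proteasome, 10 glycolysis, 8 heat shock and 7 ATF4 genes were higher. Not called by camera were immediate early genes, mitochondrially encoded mRNAs, snoRNA hosts, p53 targets and SR and CLK genes (adjusted p = 0.477, 0.270, 0.319, 0.319 and 0.270). They had 9, 1, 5, 2 and 7 members lower and 1, 0, 3, 1 and 0 higher (the same adjusted over the list alone). Without the Ribo-Zero library 15 translation factors were higher and 3 lower, and 4 were lower without 7.5 min replicate 2 or 3 and 2 without the RNase H library. Mitotic genes had 1 higher without the poly(A) library, 7.5 min replicate 2 or 7.5 min replicate 3 and 2 without replicate 1, and no glycolysis gene was higher without the poly(A) library or 7.5 min replicate 2. ATF4 targets lost camera's call without the poly(A) library (adjusted p = 0.189; adjusted p = 0.510 with an estimated correlation), 7.5 min replicate 2 (median −0.12, 0.0948; adjusted p = 0.620 with an estimated correlation) or 7.5 min replicate 3 (0.0553; adjusted p = 0.596 with an estimated correlation). Mitochondrially encoded mRNAs had 8 lower without the poly(A) library (median −3.43, camera adjusted p = 0.0170) and 4 without the RNase H library (camera adjusted p = 0.0106), and without the Ribo-Zero library their median turned from −2.19 to 0.20. SR and CLK genes had 11 lower without the poly(A) library, and immediate early genes 5 without the Ribo-Zero library or 7.5 min replicate 1.

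The 3 total libraries allow poly(A) selection to be set beside the 2 ways of depleting ribosomal RNA, with 1 library each and therefore no replicate check or test. Mitochondrial ribosomal RNA was present in the poly(A) library at levels far above those of both depleted libraries. MT-RNR2 stood at 21538 TPM in the poly(A) library, 9.64 TPM in the RNase H library and 3.78 TPM in the Ribo-Zero library. Of 30 histone genes 10 were lower with poly(A) selection against both depleted libraries, with medians of −0.92 against RNase H and −1.53 against Ribo-Zero, each at percentile 0 of random lists matched on expression. Of 53 small structured RNAs 14 were lower and 1 higher (medians −1.51 and −0.42, each at percentile 0).

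Of 11078 genes, 417 were higher and 67 lower in the poly(A) library against both depleted libraries, while RNase H exceeded Ribo-Zero for 1487 genes and fell short of it for 101. Median log2 ratios of poly(A) to RNase H and to Ribo-Zero were 0.52 and 0.79, and with median-ratio scaling 25 were higher and 141 lower. The same scaling moved the median log2 ratio of RNase H to Ribo-Zero from 0.29 to 4.10e-05 and the numbers of that pair to 950 and 250. Mitochondrially encoded mRNAs differed little between poly(A) and RNase H (median 0.12) and had a median log2 ratio of 7.27 of poly(A) to Ribo-Zero, with MT-ATP6 at 16357, 15087 and 77.54 TPM in the poly(A), RNase H and Ribo-Zero libraries. The largest poly(A) excesses after the mitochondrial ribosomal RNAs were ATP6V1G2-DDX39B (85.87, 0.5 and 9.32 TPM), HOXC4 (27.01, 3.4 and 2.21 TPM), NDUFA3 (21.19, 3.97 and 0.76 TPM) and DNAJC25-GNG10 (10.88, 1.84 and 1.68 TPM), of which ATP6V1G2-DDX39B and DNAJC25-GNG10 are read-through genes that share exons with their neighbours. The lowest ratios of poly(A) to either depleted library were those of RNU1-11P (0, 86.68 and 0.34 TPM), SNORA74A (0, 46.7 and 5.1 TPM), SCARNA1 (0, 33.32 and 2.24 TPM), SNORD10 (0, 0 and 29.66 TPM) and the pseudogenes EEF1A1P5 (2.09, 8.88 and 756.83 TPM) and RPL9P7 (0.78, 4.17 and 53.94 TPM), whose values are uncertain because of near-identical genes. MALAT1 stood at 183, 178 and 48.5 TPM.

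The authors' rates set out how genes of different kinds are made and lost. In the authors' deposited table, lncRNAs had faster degradation (median score 0.42 over 1972 genes) and slower synthesis (−0.51) than protein-coding genes (−0.10 and 0.20 over 12631 genes). Pseudogenes had a degradation score of 0.41 and a synthesis score of −0.29 in the authors' deposited table (517 genes), and the latter turned to 0.10 among genes with a mean total TPM of at least 1. Among lists, ribosomal proteins (−0.85), OXPHOS (−0.69), glycolysis (−0.57), histones (−0.53) and the proteasome (−0.53) had the lowest degradation scores in the authors' deposited table, each at percentile 0 of random lists, and nuclear lncRNAs (0.45), zinc finger genes (0.19) and immediate early genes (0.18) the highest (percentiles 99.8, 100 and 99.4). RPS2 (−0.94) and GAPDH (−0.92) stood at the stable end, and MYC (0.61), NEAT1 (0.66) and LINC02226 (2.23) at the other, in the authors' deposited table. Nuclear lncRNAs leaned to the nucleus with a cytoplasmic to nuclear score of −0.68 (percentile 0.06), SR and CLK genes had −0.32 (percentile 0.41) and histones 0.72 (percentile 100) in the authors' deposited table. Polysomal scores were lowest for mitochondrial mRNAs (−0.88) and heat shock chaperones (−0.82), each at percentile 0, and high for OXPHOS (0.54) and ribosomal proteins (0.48) in the authors' deposited table.

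Of the 7 clusters in the authors' deposited table, cluster 1 (2066 genes, 99.4% protein-coding, median degradation score −0.39) held 72 of 79 ribosomal protein, 50 of 56 OXPHOS, 29 of 31 proteasome and 20 of 22 mitotic genes. Cluster 7 of the authors' deposited table (921 genes) was 67.6% lncRNA with a median degradation score of 1.00, and cluster 3 held 247 of 398 zinc finger genes and 14 of 26 immediate early genes. The 1972 lncRNAs lay mostly in clusters 5, 6 and 7 of the authors' deposited table (26.1%, 31.1% and 31.6%). Across 13267 genes, the log2 change of total against labelled 60 min RNA had a Spearman correlation of −0.815 with the degradation score in the authors' deposited table. Both come from the same libraries, and genes are not independent replicates. The change from 7.5 to 60 min had a correlation of 0.112 with that score across 13315 genes.

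**Figure D5:**
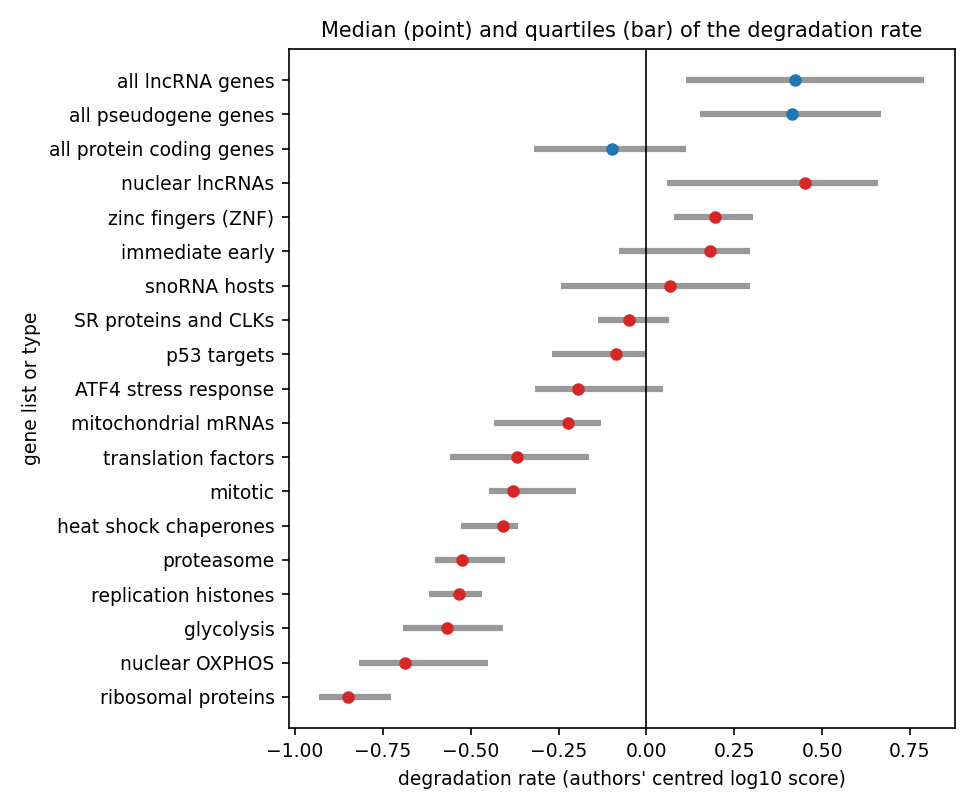
Median (point) and quartiles (bar) of the degradation score (centred log10 scale, horizontal axis) in the authors' deposited table, for gene types (blue) and gene lists (red). Ribosomal proteins have the lowest median (−0.85), and lncRNAs (0.42), pseudogenes (0.41) and the nuclear lncRNA list (0.45) the highest.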

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

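Fits without labelled 45 min replicate 2, the ratio with each kind of transcript scaled on its own median-ratio scaling of primary transcripts and leaving out libraries for the gene lists were chosen after the result was seen. Of the counts and lead values under other settings, 77 stayed within 1.5 times and 31 moved further, and on leaving out a library 106 stayed and 8 moved. Of the values of named genes under other settings, 858 kept their direction and side of the threshold, 27 passed it newly, 46 lost it and 24 reversed, and on leaving out a library these numbers were 576, 15, 46 and 17. TPM carry no read depth, so what depth limits could not be given. The cause of the values below was not tested, but quantile and median-ratio scaling set all genes' median near 0.

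With quantile normalization, labelled 60 min against 7.5 min gave 1510 genes higher and 1176 lower, total against labelled 60 min 2276 and 2511, total against labelled 7.5 min 2299 and 2369, and primary transcripts 2667 and 3709. With median-ratio scaling the same comparisons gave 1296 and 1307, 2856 and 2517, 2935 and 2702, and 3175 and 3154. With TPM rescaled over mature transcripts alone, 1588 genes were higher at 60 than at 7.5 min, and 281 were higher in total than in labelled 7.5 min RNA. The ratio with each kind scaled on its own gave 1789 higher and 2072 lower. With no filter, 923 genes were higher in total than in labelled 7.5 min RNA.

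Among named genes at 60 against 7.5 min, quantile normalization reversed the log2 changes of MT-ATP6 (−0.39), SNHG29 (−0.11), ENO1 (0.23), EEF1A1 (0.43), FOS (−0.12) and ACTB (0.0606). Median-ratio scaling reversed MT-ATP6 (−0.16), ZNF207 (−0.0857), TAF1D (−0.15), SNHG29 (−0.34) and FOS (−0.26), and rescaling over mature transcripts alone reversed MT-ATP6 (−0.0525), TAF1D (−0.0367), SNHG29 (−0.24) and FOS (−0.17). For total against labelled 60 min, quantile normalization reversed ENO1 (−0.0280), EEF2 (−0.52) and ACTB (−0.31). Median-ratio scaling reversed H1-4 (0.44), H4C15 (0.58), SNORD3A (0.42), HSPA8 (0.91), HSP90AA1 (0.83) and TOP2A (0.77).

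Leaving out in turn each library of the compared groups and labelled 45 min replicate 2, genes lower at 60 than at 7.5 min ranged from 408 to 895 (the latter without labelled 45 min replicate 2), with 408 without 7.5 min replicate 3 and 416 without 60 min replicate 1. Genes higher in total than in labelled 60 min RNA ranged from 560, without the poly(A) library, to 977, without labelled 45 min replicate 2. Genes higher in total than in labelled 7.5 min RNA ranged from 314, without the poly(A) library, to 747, with 380 without 7.5 min replicate 2. Primary transcripts higher at 60 min ranged from 56 to 117, with 57 without 7.5 min replicate 2, 56 without 60 min replicate 1 and 61 without 60 min replicate 2. Named genes that changed sign ranged, at 60 against 7.5 min, from −0.15 to 0.20 (SNHG29), −0.20 to 0.0255 (EEF1A1), −0.61 to 0.14 (COL1A1) and −0.51 to 0.41 (FOS). For total against labelled 60 min, without the poly(A) library the changes were 0.00487 (H4C15), 0.59 (SNORD3A), −0.0215 (EEF2) and −0.0829 (COL1A1). Without any other library the ranges were −2.04 to 0.0827 (MT-CO1), −0.22 to 0.0331 (HSPA8), −0.60 to 0.24 (HSP90AA1) and −0.0460 to 0.79 (COL1A1), where the positive ends of MT-CO1, HSPA8 and HSP90AA1 came without the Ribo-Zero library and the negative end of COL1A1 without 60 min replicate 2. Calls of some named genes were lost with 1 library fewer. At 60 against 7.5 min, the calls lost without 7.5 min replicate 1 were SCARNA10 (3.68), DHFRP1 (−4.03), RN7SL76P (−2.71), MDM2 (0.72), MKI67 (0.81) and AURKB (0.71). Without 7.5 min replicate 2 they were SCARNA10 (3.68), HSPA8 (0.48) and AURKB (0.65), and without replicate 3 DHFRP1 (−4.07), PSMD8 (−0.60), HSPA8 (0.64) and MDM2 (1.07). At 60 min, replicate 1 decided RN7SL76P (−2.78), HSPA8 (0.55) and AURKB (0.59), replicate 2 SCARNA10 (4.05), DHFRP1 (−3.60), MDM2 (0.93) and MKI67 (0.84), and replicate 3 SCARNA10 (3.97), DHFRP1 (−3.60), RN7SL76P (−2.78), HSPA8 (0.60), MDM2 (0.82) and MKI67 (0.86). For total against labelled 60 min, 60 min replicate 1 decided ENO1 (0.74), replicate 2 ENO1 (0.75) and MALAT1 (−1.88), replicate 3 ENO1 (0.67), MALAT1 (−1.68), MIR3648-2 (−4.19), ZNF711 (−1.03) and MDM2 (−0.91), the poly(A) library ENO1 (0.49), the RNase H library MIR3648-2 (−4.48), and the Ribo-Zero library MIR3648-2 (−4.33), ZNF711 (−1.08), MALAT1 (−1.44), HSPA5 (−0.51) and MDM2 (−0.85). The primary transcript of ATP2A1-AS1 lost its call without any of 5 libraries, with 1.27 without 7.5 min replicate 2, 1.82 without 7.5 min replicate 3, and 1.57, 1.79 and 1.75 without 60 min replicates 1, 2 and 3.

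The replicate letters were tried as a block. Libraries with the same letter correlated across times at 0.20 to 0.34 (A), −0.01 to 0.10 (B) and 0.09 to 0.29 (C) after removal of the time means. Not every correlation was over 0.1, so the letters were not used as pairs. As a hint from the data and not the design, all 5 libraries of A, 3 of 5 of B and all 5 of C correlated best on average with their own letter. The replicate block raised the genes called at 60 against 7.5 min from 3358 to 4759, and heat shock chaperones passed camera (adjusted p = 0.0231). With the replicate block 1090 genes were lower at 60 than at 7.5 min, 4473 changed over labelling time and 158 primary transcripts were higher.

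With an estimated correlation camera called 3 lists for labelled 60 min against 7.5 min, 3 for total against labelled 60 min and 1 for total against labelled 7.5 min, where fry called 5. With median-ratio scaling 25 genes were higher and 141 lower in the poly(A) library than in both depleted libraries. Of the authors' rates by gene type and list, 82 values kept their direction and side, 7 passed newly, 14 lost it and 2 reversed. With random lists matched on mean TPM, 8 lists lay outside the central range for synthesis and the OXPHOS percentile was 0.03. Among genes with a mean total TPM of at least 1, the pseudogene synthesis median was 0.10.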

Other observations

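The scaling test of ribosomal protein and OXPHOS mRNAs, the test of the copies table and all counts over other splits of the libraries were chosen after the result was seen. Other introns in the authors' deposited table also had a lower excised share at 30 than at 7.5 min. For proteasome genes these were 107 of 188 introns, for OXPHOS genes 67 of 110 and for glycolysis genes 47 of 98, against 17 of 216 for mitotic genes, 8 of 188 for zinc finger genes and none of 9 for immediate early genes. The PSMB4 intron on chromosome 1 at 151373065 to 151373239 (hg19) stood at 64.2%, 17.7% and 27.6% at 7.5, 30 and 60 min in the authors' deposited table. Across 21782 introns of that table, the excised share at 60 min had a Spearman correlation of 0.34 with the distance score from the transcription start, of 0.31 with that to the poly(A) site and of −0.23 with GC content. At 7.5 min these correlations were −0.0217, −0.0373 and 0.20, and introns are not independent replicates.

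Ribosomal protein and OXPHOS mRNAs were lower at 60 than at 7.5 min, with a median log2 change of −1.30 over 145 genes. Genes of like span and expression stood at 0.38, so a shorter path to a finished transcript gave −8.72% of the lists' change (95% bootstrap interval −12.8% to −1.74%), which argues against short genes being finished first, though the match was incomplete (median log10 span 4.10 against 3.86 in the lists and 4.43 in all genes, log2 TPM 5.61 against 7.06). The scalings argue against library scaling as the cause, since the highest median under the other 3 was −1.25. Carry-over of unlabelled RNA stays open, and introns less excised at 30 than at 7.5 min go with it (276 of 307 ribosomal protein, 67 of 110 OXPHOS). Other genes (602) with like ratios of total to labelled RNA gave 40.1% of the lists' change (31.2% to 54.8%), between the bounds of 25% and 50%. The match was incomplete (median log2 ratio 0.77 against 1.38, log2 TPM 5.52 against 7.06). A biological cause also stays open and was not tested.

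Labelled 45 min replicate 2 lay apart from the other labelled libraries, with a median correlation of 0.797 against 0.837 to 0.913. Of the tested genes 2545 were at 0 TPM in it, against 618 to 1114 in the other 14, which is consistent with fewer features detected. Against a few genes taking most of the TPM, its top 10 transcripts held 20.5%, within the range of 13.5% to 31.99%. No biological explanation was tested. Without it 3001 genes were higher and 895 lower at 60 than at 7.5 min.

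In the authors' deposited table of copies per cell, as read here, values of intronless genes could be shifted between columns. Rows were split at white space, which closes up any empty fields. As read, all 25068 intronless genes had no value in the 3 poly(A) columns. The value under the RNase H mature heading equalled the RNase H TPM times its factor, within 5%, in 0% of 438 genes, so that heading, as read, does not hold for them. The values under the Ribo-Zero locus and mature headings equalled the Ribo-Zero product in 68.3% of 369 genes, that under the Ribo-Zero primary heading equalled the RNase H product in 80.4% of 438 genes, and that under the RNase H mature heading equalled the poly(A) product in 33.6% of 473, with quartiles of their ratio of 0.922 and 1.08. These values go with a shift made by this reading, so they show no fault in the deposit. The 33.6% lies between the bounds of 10% and 90%. It cannot decide, with a tolerance as wide as the spread of the poly(A) factor (quartiles 0.0933 and 0.103). The authors' rate table matched, within 0.05 on the log10 scale, the mean over the 3 libraries in 97.9% of 907 single-exon genes and the mean of the Ribo-Zero and RNase H mature headings in 5.29%, and no biological explanation was tested.

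In genes with at least 3 introns in the authors' deposited table, the first intron had a higher excised share than the last at 7.5 min in 50.8% of 2473 genes, and at 60 min in 43.4%. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Only 1 split, the real one, called as many genes in each of these comparisons. The real and the highest other numbers were 3358 and 1 for labelled 60 min against 7.5 min, 7522 and 0 for total against labelled 60 min, and 4764 and 0 for total against labelled 7.5 min. For primary transcripts they were 10966 and 0, and for the ratio 8875 and 0. For any change over time, only the real split of 100 called as many genes (2720, next 116). This argues against chance in these libraries.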
